A study of Drosophila melanogaster with 6 samples.

How the data were processed

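RNA from whole larvae early in the third instar was measured on 6 oligonucleotide arrays, 3 from control larvae of the w1118 strain and 3 from larvae with a heat-inducible DHR96 transgene, grouped as in the labels. The deposited values are intensities on a linear scale, 1 per probe set and array. They were made with GCRMA, per the submitters' processing notes, which give no version. The scanner settings and a genome build are not given in the sources used here. The deposited intensities ran from 2.54 to 86990. The precision of the comparison is limited by the number of arrays.

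Genes were named from the platform annotation. Of 18952 probe sets 13647 had 1 gene, 402 several, 4720 none listed and 183 were controls of the array. Of those with 1 gene, 13544 matched by gene ID a reference table of the Release 6 plus ISO1 MT assembly, used only for symbols and the order of neighbouring genes. Probe sets with several genes or none were tested and counted but given no gene name.

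Log2 values were taken with no pseudocount. A probe set was tested when its log2 value was 4 or more on at least 3 of the 6 arrays, and control probe sets were left out, which kept 8395. The brightest probe set of a gene was used, which left 7974 tests, of 7010 genes with a name, 238 probe sets with several genes and 726 with none. Gain and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. All adjusted p-values of genes are from limma. Where a whole group lay below the floor of 4, the fold is given as at least the ratio of the other group's mean to that floor. Where some arrays of a group did, they were held at the floor for the fold or difference given for a gene, and the tests and the order of genes used the measured values. Gene lists with 5 or more tested members, 30 in number, were tested with limma's camera (preset correlation 0.01), with p-values adjusted over the lists; camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance by rotations, were alternatives. For these 30 lists fry was run only on the deposited values and was not repeated after centring. Tables were made in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and figures with Matplotlib 3.10.9.

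The groups, the test, the filter, the gene lists, the planned settings and the rule for named genes were fixed before the data were examined. The rule names Hr96 and white, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 members of each list with the largest differences; other called members complete a count. The planned settings were no filter, a floor of 6, quantile normalization, median centring of arrays, an intensity trend, robust hyperparameters, array weights, the mean of a gene's probe sets, every probe set on its own, the replicate number as a block, a pseudocount of 16 and each array left out in turn. Added after the data were seen were leaving out control 3 and gain 2 together, averaging controls 1 and 2, and median difference centring, which shifts each array by its median difference from the mean array.

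The procedure was tested on data simulated for gain against control over the same 7974 tests, with 50 genes changed at each size. It called 4 of 50 genes changed 1.41-fold, 26 of 50 changed 2-fold, 49 of 50 changed 4-fold and 49 of 50 changed 16-fold, with 2 false calls. With the P450 list shifted down by 0.5 on the log2 scale in simulated data, camera called 1 list, the shifted one. The simulated genes were drawn independently of each other, while the correlation estimated for the P450 list in the real data was 0.225. The simulations therefore do not show how the tests behave when genes are correlated.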

Results

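Messenger RNA was measured with oligonucleotide arrays in whole Drosophila melanogaster larvae early in the third instar, fed on yeast. The 3 gain samples carried a heat-inducible transgene with the full-length cDNA of Hr96, the gene for the nuclear receptor DHR96. The 3 control samples came from the w1118 host strain without the transgene. Both groups were kept at 37.5 °C for 1 h, starting 3 h after the moult, and RNA was taken 4 h later. The comparison asks which transcripts differ when DHR96 is expressed in excess. No uninduced transgenic larvae were analysed here, so induced DHR96 and any standing difference between the transgenic line and its host enter each value together. The labels give no finer stage of the larvae, so any difference in stage between the groups would enter too. Each array gave values for 18952 probe sets, of which 44.5% to 45.0% lay at or above a log2 value of 4. The labels do not say that the samples of a group came from separate cultures.

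In larvae with induced DHR96 the signal of 3 trypsin genes of the midgut was near background, and that of several genes of sterol and neutral lipid handling was lower. Hr96 itself was 34.2-fold higher, with log2 values of 9.47, 9.82 and 9.50 in control and 14.73, 14.71 and 14.64 in gain, a log2 difference of 5.10 ± 0.13 (SE, n = 3 per group, adjusted p = 1.86e-05). The trypsin gene epsilonTry was at least 1818-fold lower (adjusted p = 9.44e-05), and Npc2c, of a family of sterol-binding proteins, had a log2 difference of -3.42 ± 0.29 (adjusted p = 0.0045). Of 7974 genes and unnamed probe sets tested, 36 were higher in gain larvae and 277 lower, of which 26 and 168 differed at least 2-fold; median centring of the arrays gave 201 higher and 252 lower, and calls numbered 39 without control 1 and 59 without control 2. The white gene, a common marker of such transgenes, had no probe set named for it and was not analysed here.

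**Figure D1:**
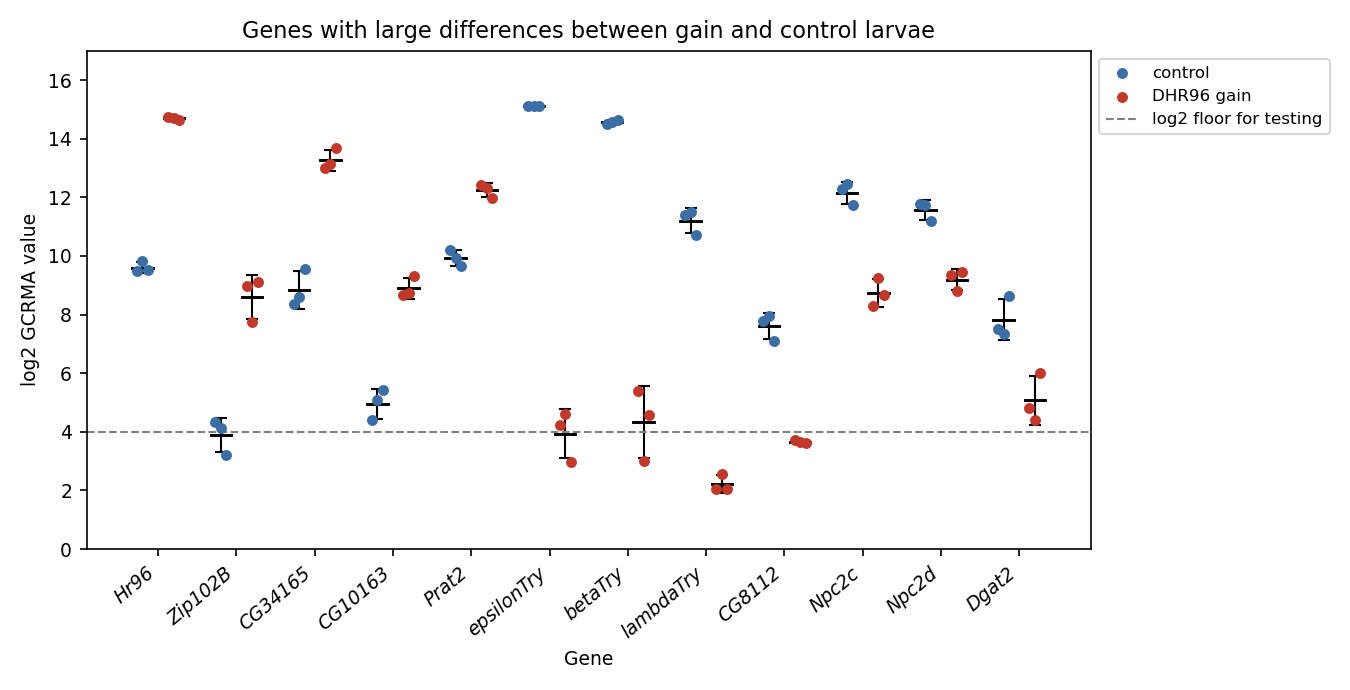
Log2 GCRMA values (vertical axis) of 12 genes on the 3 control arrays (blue) and 3 gain arrays (red), each point an array, with group means and SDs in black and the log2 floor of 4 for testing dashed. Hr96 has a mean of 9.60 in control and 14.69 in gain, and epsilonTry 15.11 and 3.94.

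After Hr96, the largest rises among named genes were in Zip102B, of the zinc transporter family, and in CG34165 and CG10163. Zip102B, with 1 control array below the floor, had a log2 difference of at least 4.46 (adjusted p = 0.0063), and CG34165 and CG10163 had log2 differences of 4.43 ± 0.34 and 3.94 ± 0.30 (SE, n = 3 per group, adjusted p = 0.00337 for both). Prat2, which encodes the enzyme that starts purine synthesis, rose by 2.31 ± 0.19 (adjusted p = 0.00356). CG7763 rose by 2.84, CG15282 by 2.45, CG3726 by 1.75, CG3168 by 1.66, CG17571 by 1.39 and Srg2 by 1.37, with adjusted p-values from 0.00921 to 0.0424. CG31468 lay below the floor in control larvae and was at least 1.93-fold higher in gain (adjusted p = 0.0098). A probe set with no gene listed, singled out after its values were seen, lay below the floor in control and at 16.05 to 16.15 in gain, at least 4371-fold higher (adjusted p = 3.61e-07); the annotation does not say which sequence it reads, so sequence of the transgene itself is not excluded. Without control 1 the calls of CG7763, CG15282, CG31468, CG3726, CG3168, CG17571 and Srg2 ended, and without control 2 those of CG7763, CG15282, CG31468, CG3168 and Srg2. CG7763 also lost its call without gain 1 or gain 2, CG17571 without gain 1 or gain 3, and Srg2 held only without gain 2.

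The 3 largest falls were in trypsin genes, which encode digestive proteases. The log2 value of epsilonTry was 15.11 ± 0.00847 in control and 3.94 ± 0.85 in gain (mean ± SD, n = 3), and that of betaTry 14.58 ± 0.0779 and 4.33 ± 1.22. Each had 1 gain array below the floor, and betaTry was at least 964.5-fold lower (adjusted p = 0.00123). The gene lambdaTry lay at 11.20 in control and below the floor in gain, at least 147-fold lower (adjusted p = 3.03e-05), and iotaTry had a difference of -0.81 (adjusted p = 0.0243). Of 27 midgut serine proteases tested these 4 fell and none rose, and adjusted over the list alone 4 were lower and 1 higher. The gene thetaTry, which lies between lambdaTry and epsilonTry, had means of 10.06 in control and 11.56 in gain without passing (adjusted p = 0.0561), and kappaTry, zetaTry, etaTry and alphaTry, also between them, had gain means of 11.21, 11.43, 11.14 and 12.67. The list did not pass camera (adjusted p = 0.935) and was lower by fry (adjusted p = 0.0171). Its median of -0.09 lay above that of all tests, -0.15. Under median centring the list's median was 0.16, against 0.10, and under median difference centring 0.06, against -0.0009. The list's mean, with lambdaTry at its bound, was -1.05. Trypsin genes resemble each other, so a probe set can also read a near copy, and the call of iotaTry held only without control 3 or gain 3.

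**Figure D2:**
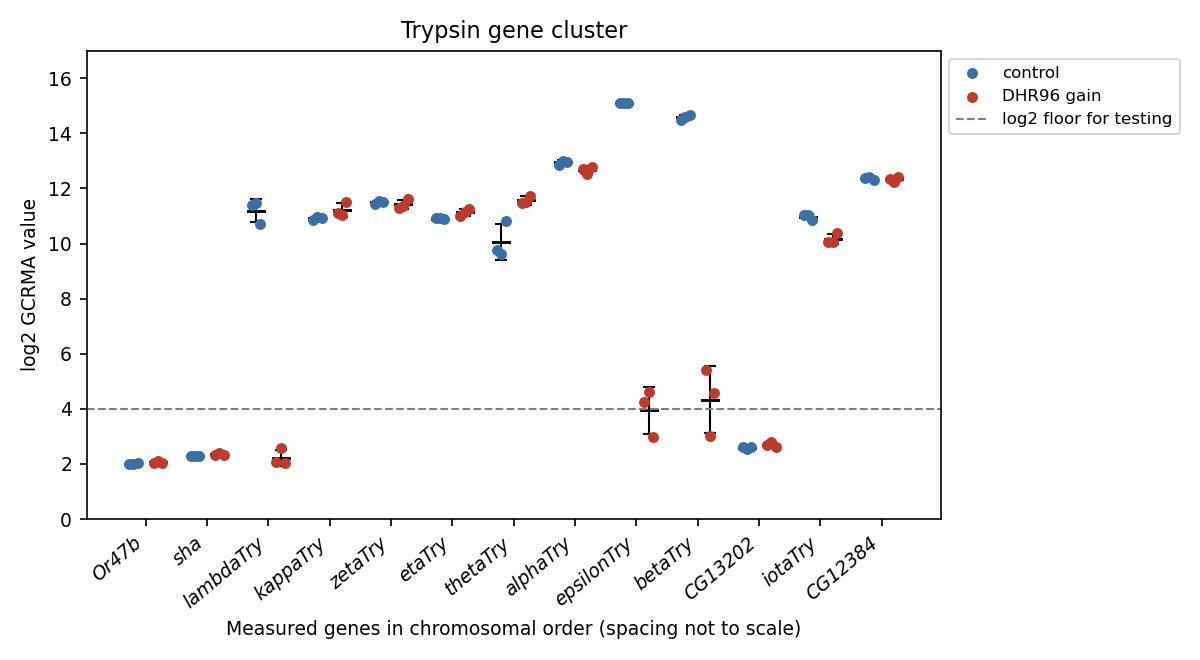
Log2 GCRMA values (vertical axis) of measured genes of the trypsin cluster in chromosomal order (horizontal axis, not to scale) on 3 control arrays (blue) and 3 gain arrays (red), with group means and SDs in black and the log2 floor of 4 dashed. On the gain arrays lambdaTry, epsilonTry and betaTry lie between 2.03 and 5.40, and the 5 genes between lambdaTry and epsilonTry between 11.01 for etaTry and 12.79 for alphaTry.

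Sterol and neutral lipid genes stood among the other large falls. CG8112, of the sterol acyltransferase family, lay at 7.60 in control and below the floor in gain, at least 12.2-fold lower (adjusted p = 0.00131). Npc2c lay at 12.15 in control and 8.73 in gain, Npc2d had a log2 difference of -2.38 ± 0.24 (SE, n = 3 per group, adjusted p = 0.00749), and Npc2e one of -0.62 (adjusted p = 0.0463). Of 24 genes of sterol and lipoprotein transport these 4 fell, none rose and 20 did not pass, among them the scavenger receptor gene santa-maria at -1.11 (adjusted p = 0.215). Adjusted over the list alone, 7 were lower. The list had a median of -0.26 and did not pass camera (adjusted p = 0.107) but was lower by fry (adjusted p = 0.0383). Fry was run on the deposited values, where the median of all tests was -0.15. Median centring moved the list's median to -0.02 and that of all tests to 0.10. On control 3 the median of this list differed by -0.19 from the other controls. Dgat2, which encodes an enzyme of the last step of triacylglycerol synthesis, had a difference of -2.75 ± 0.50 (adjusted p = 0.0389), Seipin -0.88 (adjusted p = 0.015) and CG1941, which neighbours Dgat2, -0.74 (adjusted p = 0.0285). Of 22 genes of triacylglycerol synthesis and storage these 3 fell and 19 did not pass, Lpin among them at -0.79 (adjusted p = 0.0889). Over the list alone 5 were lower, the median was -0.43 and camera gave an adjusted p of 0.0599; on control 3 the list's median lay 0.28 above the other controls. Without control 1, control 2 or gain 1 the calls of Npc2e, Dgat2, Seipin and CG1941 ended; Npc2e held only without control 3, and Dgat2 and CG1941 only without gain 3. Median centring and quantile normalization also ended the calls of Npc2e and CG1941.

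Of 17 acid and neutral lipases tested, 2 fell and 15 did not pass. Camera called the list lower (adjusted p = 0.00648), a call lost with an estimated correlation (adjusted p = 0.92 with an estimated correlation) and with no filter (adjusted p = 0.0509), and by fry the adjusted p was 0.0171. The list's median was -0.49, against -0.15 for all tests, and 16 members had a negative difference. The 2 that fell were CG5162, at -1.44 ± 0.13 (SE, n = 3 per group, adjusted p = 0.00623), and CG5966, below the floor in gain and at least 2.22-fold lower (adjusted p = 0.0045). CG8093 and CG2772 had differences of -0.90 and -0.79 without passing. Adjusted over the list alone, 9 were lower. On control 3 the median of the lipases differed by -0.16 from the other controls. None of 26 fatty acid oxidation genes passed (camera adjusted p = 0.935), with Mfe2 at -0.50, Acox3 at -0.39 and a median of -0.16. Under median centring and quantile normalization that median was 0.09 and 0.01, against 0.10 and 0.04 for all tests. Outside these lists, sit, a fatty acid elongase gene, had a difference of -3.17 ± 0.39 (adjusted p = 0.0111), CG5157 -3.07 (adjusted p = 0.0146), and CG11438, of the phosphatidate phosphatase family, -2.69 ± 0.18 (adjusted p = 0.00254). CG14893 lay below the floor in gain and was at least 2.84-fold lower (adjusted p = 0.00749), and CG14439, with 2 gain arrays below it, at least 5.39-fold lower (adjusted p = 0.0111). Without control 1 or control 2 the calls of sit, CG14439 and CG5157 ended, and that of CG5157 also without gain 1 or gain 2.

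Several genes of xenobiotic metabolism were lower in gain larvae. Of 45 cytochrome P450 genes 7 fell and none rose: Cyp6a22 at -1.36 ± 0.16 (SE, n = 3 per group, adjusted p = 0.0098), Cyp4c3 at -1.10 ± 0.20 (adjusted p = 0.041), Cyp9b2, Cyp12a5, Cyp317a1, Cyp305a1, and Cyp9h1, below the floor in gain and at least 1.10-fold lower. Cyp49a1 and Cyp6a2 had differences of -1.28 and 1.10 without passing (adjusted p = 0.15 and 0.107). The P450 median was -0.31, or -0.30 with Cyp9h1 at its bound, and on control 3 it differed by -0.14 from the other controls. Of 21 UDP-glucuronosyltransferases 3 fell, Ugt303B3 at -1.58 (adjusted p = 0.0045), Ugt37C1 at -1.57 (adjusted p = 0.0174) and Ugt304A1 at -0.59, while Ugt37E1 had a difference of 1.61 without passing (adjusted p = 0.0644). Of 11 carboxylesterases and epoxide hydrolases 3 fell, alpha-Est8 at -2.84 ± 0.54 (adjusted p = 0.0433), alpha-Est10 at -1.27 and alpha-Est3 at -0.69. On control 3 alpha-Est8 lay at 5.74, against 7.71 and 7.79 on the other controls. Of 7 efflux transporters Mdr49 fell, at -0.97 (adjusted p = 0.0242), and CG10505 had a difference of -3.10 ± 0.66 without passing (adjusted p = 0.0584). Of 30 glutathione S-transferases GstD5 rose by 0.86 (adjusted p = 0.00961) and 29 did not pass. Adjusted over each list alone, 8 P450 genes, 5 glucuronosyltransferases, 4 esterases and 2 transporters were lower, and 1 P450 gene, 1 glucuronosyltransferase and 1 glutathione transferase higher. None of the 5 lists passed camera (adjusted p from 0.107 to 0.935). The medians of glucuronosyltransferases, esterases and glutathione transferases, -0.22, -0.18 and -0.07, became 0.03, 0.07 and 0.18 under median centring. That centring put the median of all tests at 0.10. Glucuronosyltransferases and esterases thus still lay below all tests, and glutathione transferases above. Without control 1 or control 2 the calls of all the genes named here that passed ended except that of Ugt303B3; Cyp12a5, Cyp317a1, alpha-Est3 and alpha-Est8 held only without control 3, Cyp9b2 and Cyp305a1 only without gain 3, Cyp4c3 only without either of these, Ugt304A1 in no such fit, and Mdr49 was also lost without gain 1. Median centring ended the calls of Cyp4c3, Cyp9b2, Cyp12a5, Cyp305a1, Ugt304A1 and alpha-Est3.

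Among nuclear receptors other than DHR96, 2 of 10 fell. Hr39 had a difference of -1.05 ± 0.19 (SE, n = 3 per group, adjusted p = 0.0365), and Hr38 lay below the floor in gain, at least 2.70-fold lower (adjusted p = 0.024). The genes svp and ftz-f1 had differences of -0.81 and -0.80 without passing, and the median was -0.41. Hr38 and Hr39 were also the 2 of 11 ecdysone response genes that fell, and vri had a difference of 1.09 without passing (adjusted p = 0.0544). Adjusted over the list alone, 5 receptors were lower and 1 higher, and 2 ecdysone response genes lower and 1 higher. Camera gave adjusted p-values of 0.107 and 0.38. None of 6 ecdysteroid synthesis genes passed (camera adjusted p = 0.96), with Npc1a at -0.38. On control 3, 9 of the 10 receptors lay below their mean on the other controls. Without control 1, control 2 or gain 1 the calls of Hr38 and Hr39 ended, that of Hr38 also without gain 2 and that of Hr39 without gain 3. Both also ended with no filter, with the replicate number as a block and with controls 1 and 2 averaged. The call of Hr39 ended with the mean of its probe sets too. That of Hr38 ended with a floor of 6 and without control 3 and gain 2.

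Of 58 cuticle protein genes tested, 6 fell and 52 did not pass. Camera called the list lower (adjusted p = 0.00648), a call lost with an estimated correlation (adjusted p = 0.92 with an estimated correlation) and by fry (adjusted p = 0.0874). Cpr78Ca had a difference of -2.38 ± 0.25 (SE, n = 3 per group, adjusted p = 0.0083), Cpr67Fa1 -1.22, Cpr97Eb -1.10, Cpr67Fa2 -0.90, TwdlN -0.87 and Cpr49Af -0.65. Cpr65Au had the largest difference of the list, -2.92, without passing (adjusted p = 0.0585). Of the 58 genes 53 had a negative difference, the median was -0.48, against -0.15 for all tests, and 11 were lower adjusted over the list alone. All 7 male germline genes tested had a negative difference, with a median of -0.46, and 2 fell, which were also the 2 lower over the list alone: ocn, at least 2.85-fold lower (adjusted p = 0.00337), and betaTub85D, a tubulin gene of the testis, at least 2.73-fold lower (adjusted p = 0.0287), both below the floor in gain. Camera called the male germline list lower (adjusted p = 0.0172), a call lost with an estimated correlation (adjusted p = 0.92 with an estimated correlation) and with no filter (adjusted p = 0.415), and by fry the adjusted p was 0.0171. On control 3, 6 of the 7 male germline genes lay below their mean on the other controls. Without control 1 the calls of the 6 cuticle genes and betaTub85D ended; Cpr97Eb, TwdlN and betaTub85D held only without control 3, Cpr49Af only without gain 2 and Cpr67Fa2 only without control 3 or gain 3, and Cpr67Fa1 was also lost without control 2 or gain 1. Median centring ended the calls of Cpr97Eb, Cpr67Fa2 and Cpr49Af.

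Camera called 3 lists higher in which at most 1 member passed, and all 3 calls were lost with an estimated correlation (adjusted p = 0.92 with an estimated correlation). InR, the insulin receptor gene, rose by 0.90 ± 0.14 (SE, n = 3 per group, adjusted p = 0.0226), the only one of 14 insulin signalling and FOXO target genes to pass, while conv, ImpL2 and REPTOR had differences of -0.99, 0.65 and 0.62. None of 16 heat shock and chaperone genes passed, with CG7130 at 0.68 (adjusted p = 0.058), Hsp68 at 0.24 and stv at 0.22. None of 57 genes of mitochondrial oxidative phosphorylation passed either, with UQCR-11 at 0.59 (adjusted p = 0.199) and SdhB at -0.21. The medians of the 3 lists were 0.04, 0.03 and -0.03, against -0.15 for all tests (-0.05 without gain 2), and camera's adjusted p-values 0.0213, 0.0181 and 0.0213. By fry they had adjusted p-values of 0.613, 0.52 and 0.801. The median and mean of oxidative phosphorylation lay below 0 while camera, which sets a list against other genes, pointed up, and the median turned positive under the 3 other scalings. Adjusted over the list alone, 2 insulin pathway genes were higher and 1 lower, and 1 heat shock gene higher. The insulin call was also lost without control 3 (adjusted p = 0.112), without control 3 and gain 2 (0.148), with median centring (0.0687), array weights (0.0539) and no filter (0.968). That of heat shock was lost without gain 2 (adjusted p = 0.0564), without control 3 and gain 2 (0.0721), with quantile normalization (0.221) and with no filter (0.79). That of oxidative phosphorylation was lost without control 1 (adjusted p = 0.0563) or gain 3 (0.128), with quantile normalization (0.0735) and with no filter (0.676). InR held only without control 3 or gain 3.

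**Figure D3:**
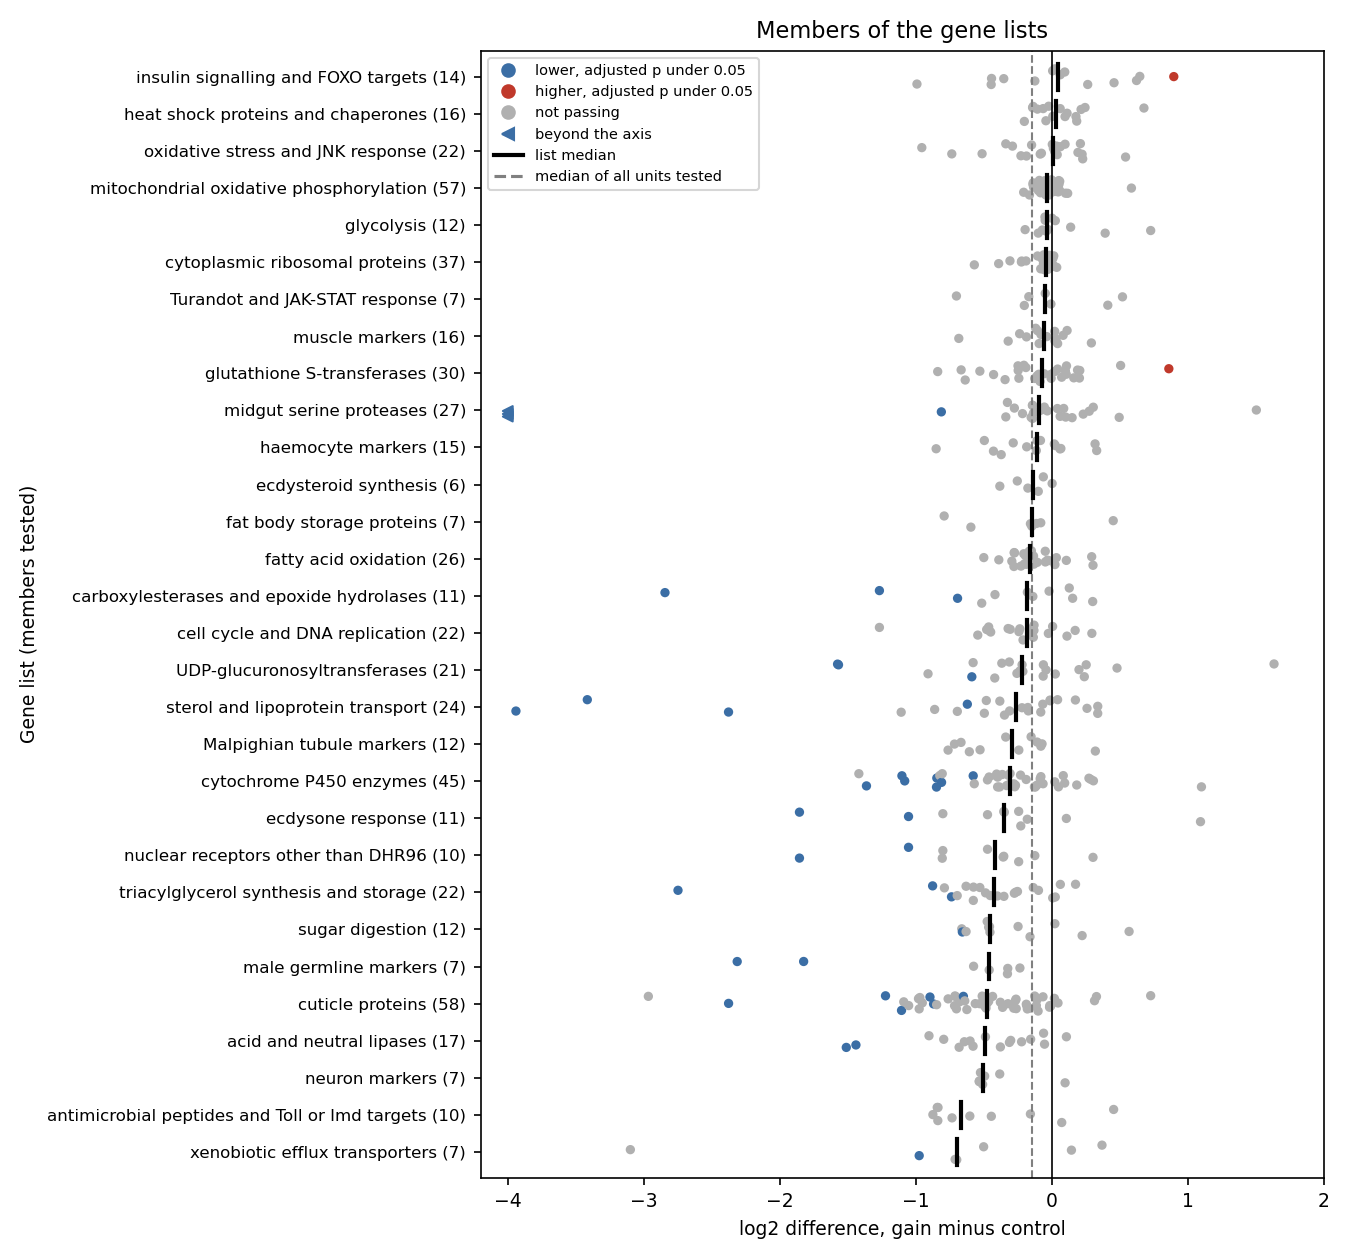
Log2 difference, gain minus control (horizontal axis), of each tested member of 30 gene lists (vertical axis, members tested in brackets); points are genes at measured values, blue if lower and red if higher at an adjusted p under 0.05, triangles lie beyond the axis, black bars are list medians and the dashed line is the median of all tests, -0.15. List medians run from -0.70 for efflux transporters to 0.04 for insulin pathway genes, and those between -0.22 and -0.03 turn positive under at least 1 other scaling. Median centring also moves the median of all tests to 0.10, so a change of sign need not be a change relative to all tests.

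Markers of other tissues and processes gave no list that passed camera. Of 12 sugar digestion genes Mal-A2 fell, at -0.66 ± 0.11 (SE, n = 3 per group, adjusted p = 0.0345), and Amyrel and Mal-A3 had differences of -0.66 and -0.63 without passing. Over that list alone 6 were lower, and the adjusted p was 0.116 by camera and 0.0383, lower, by fry. None passed among 12 glycolysis genes, where Hex-C had a difference of 0.73 (adjusted p = 0.0512), among 22 oxidative stress and JNK response genes, where egr and Sod3 had -0.96 and -0.74, or among 22 cell cycle genes, where fzy had -1.27. None passed among 37 ribosomal protein, 16 muscle, 15 haemocyte, 12 Malpighian tubule, 7 neuron or 7 Turandot and JAK-STAT genes. Adjusted over the list alone, 6 tubule genes and 1 neuron gene were lower and 1 glycolysis gene higher. Camera's adjusted p-values for these lists ran from 0.0599 for glycolysis to 0.96 for the cell cycle. None of 10 antimicrobial peptide and immune genes passed (camera adjusted p = 0.96), with a median of -0.67, and on control 3 their median differed by -1.10 from the other controls. None of 7 fat body storage genes passed (camera adjusted p = 0.843), and on control 3 their median lay 0.53 above the other controls. The salivary gland list had fewer than 5 tested members, none of which passed. The call of Mal-A2 held only without gain 3 among the fits that leave out an array, and ended under median centring and quantile normalization.

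Over all 7974 tests 1681 had an unadjusted p under 0.05 by limma. In 30.7% all gain arrays lay on 1 side of all control arrays, where chance gives 10% on average. Every gain array had a lower median over the tests than the control arrays, at 9.09 to 9.10. An offset of whole arrays can raise that share, so the contrast with 10% is not a test. Of the calls 88.5% were lower in gain; centring each array on its median gave 201 higher and 252 lower, 55.6% lower, and median difference centring 73.2% lower. The median log2 difference of all tests was -0.15 as deposited, 0.10 after median centring, -0.05 without gain 2 and -0.03 without control 3 and gain 2, so most of this shift rests on gain 2. Control 1 and control 2 differed over 2-fold in 31 tests, and control 3 from them in 228 and 302. The labels do not say whether controls 1 and 2 are separate cultures. If they are not, the SEs given with n = 3 per group are too small. Without control 3, where controls 1 and 2 alone remain, 51 were called higher and 374 lower. Calls numbered 39 without control 1, 59 without control 2, 135 without gain 1 and 53 with controls 1 and 2 averaged. Gain 2 had a median of 8.61 over the tests, against 8.95 and 8.99 for the other gain arrays, and with control 3 and gain 2 left out 129 were higher and 631 lower.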

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

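In this part the tests of the trypsin genes and of control 3, and median difference centring, were chosen after the results were seen. Among probe sets left out of testing, none met the rule for a signal outside the main measurement. That rule asked for a call with a rise of at least 2-fold in gain and all gain arrays above all control arrays. At least 2 gain arrays also had to reach the floor of 4. A probe set that reached the floor on all 3 gain arrays had already passed the filter for testing. The empty result for dim probe sets therefore says little. No such rule was run for outlying samples. Of the 183 control probe sets of the arrays limma called 0, with 4 at an unadjusted p under 0.05 and a largest log2 difference of 0.66. Of 10374 dim probe sets left out of testing 1 was called, and 0 at 2-fold or more.

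The real grouping of the arrays gave 313 calls and the highest of the other 9 splits into 3 and 3 gave 0. As many calls came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.

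On the gain arrays epsilonTry, betaTry and lambdaTry lay at or near the floor. A single deletion over the 3 genes is argued against by the 5 measured genes between lambdaTry and epsilonTry, each above a log2 value of 8 on all gain arrays. Separate gene losses, or sequence differences at the probes between the transgenic line and its host, may account for it. The highest gain value of the 3 genes was 5.40, but the genes were picked for their low gain values. That value therefore does not test the explanation. Repression by induced DHR96 stays open too. If it began with the heat, epsilonTry RNA would need a half-life of at most 26.9 minutes over the 5 h from then to extraction. With the gain array below the floor held at it, the limit is 27.7 minutes. No half-life was measured, and neither was DHR96 from the transgene before the heat. The last explanations cannot be told apart, since no uninduced transgenic larvae were analysed here.

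More genes were called lower than higher in gain larvae. Gain 2 alone is argued against, since without it 81.7% of the calls were lower. Array scaling may account for part of the imbalance: after median centring 55.6% of the calls were lower, which met the bound set beforehand, and after median difference centring 73.2%. Those shares moved mainly because higher calls went from 36 to 201 and 128, while lower calls went from 277 to 252 and 349. A share that the choice of centring sets does not decide the cause, and the part of scaling stays open.

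Control 3 stood apart from the other controls, with ng3 at 7.71 against 11.86 and 12.25, and Lsp2 at 14.45 against 13.16 and 11.64. On the gain arrays ng3 lay at 10.15 to 10.93, ng1 at 11.39 to 12.59 and ng2 at 11.46 to 12.05. Each of these ranges lay between control 3 and the other controls. Lsp2 lay on the gain arrays at 12.10 to 12.62, between control 1 and control 2. For the ng genes the gain arrays thus differed from controls 1 and 2 in the same direction as control 3. A mislabelled gain array is argued against by Hr96, at 9.50 on control 3. Larvae further into the third instar might differ this way, but only 4 of 7 fat body storage genes were higher on control 3 than on both other controls, between the 6 that the explanation needs and the 3 that would argue against it. The labels give no finer stage, so this stays open. A difference in stage between gain and control larvae was not tested.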

How the results depend on the processing

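Median difference centring, averaging controls 1 and 2 and leaving out control 3 and gain 2 were chosen after the data were seen. Hr96 was called in every setting, with log2 differences from 5.03 to 5.34. In 19 settings that could be compared gene by gene, 0 of the 313 calls changed sign. An intensity trend, robust hyperparameters or the replicate block leave a gene's difference the same, so its sign could not change there. In all 19 settings 11 higher and 19 lower calls were kept, and 11 and 24 in each fit that leaves out an array. Leaving out each array in turn gave 12 to 51 higher, 27 to 374 lower, 39 to 275 genes changed at least 2-fold (194 in the full data), 2 to 4 lists higher and 3 to 4 lower. With no filter, which tests more, 17 were higher, 85 lower and 70 changed at least 2-fold; with array weights 638, 1928 and 352; with controls 1 and 2 averaged, which leaves fewer arrays, 13, 40 and 53. Higher counts were 170 with quantile normalization, 201 with median centring, 128 with median difference centring and 129, with 631 lower, without control 3 and gain 2. Lists called higher numbered 0 with an estimated correlation, by fry and with no filter, 1 with quantile normalization and 5 with median difference centring. Lists called lower numbered 0 with an estimated correlation, 5 by fry, 11 with no filter, 8 with median centring, and 6 with quantile normalization or without control 3 and gain 2. The list: mitochondrial oxidative phosphorylation reversed by fry (adjusted p = 0.801) and with no filter (adjusted p = 0.676), in a range of adjusted p over its alternatives from 6.23e-06 to 0.92. The reversal by fry follows from the test: fry sets the list against 0, where its mean was -0.02, and camera sets it against other genes. Apart from this, the fewer arrays and the added tests, the cause of these changes was not tested. Among single named genes 0 reversed in any setting; 178 comparisons fell short of the threshold and 65 newly passed it in settings with all arrays or the added ones, and 230 and 13 in fits that leave out an array. With the replicate number as a block 41 were higher and 217 lower, and 205 of these 258 were among the 313. Same-numbered samples deviated from their group means with correlations of 0.21, 0.0255 and 0.367. Controls 1 and 2 both correlated best with gain 1 (0.21 and 0.343), and control 3 with gain 3. Deviations from a mean of 3 arrays are tied to each other, so these values do not settle whether the numbers pair the samples. Signal over background limits genes below the floor to bounds.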

Other observations

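In this part the gene families and the genes named were chosen after the calls were seen. The family tests first asked only for a p under 0.05; adjustment over the 5 families, the repeat after median difference centring, the repeat without any called member, and the exception for runs of related neighbours were set after the first results.

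The genes in this paragraph were picked from the 313 calls, and whether genes of their kind are more frequent among the calls was not tested. Sox14, an ecdysone-induced transcription factor gene, had a log2 difference of -2.30 ± 0.27 (SE, n = 3 per group, adjusted p = 0.0098), exex, a homeobox gene, -1.82 ± 0.19 (adjusted p = 0.0083) and hh, which encodes the Hedgehog ligand, -1.54 ± 0.11 (adjusted p = 0.00265). GATAe and cad, transcription factor genes of the gut, had differences of -1.29 ± 0.12 (adjusted p = 0.0063) and -1.02 ± 0.12 (adjusted p = 0.00965). For each of these genes all gain arrays lay below all control arrays. Without control 1 the calls of Sox14, exex, GATAe and cad ended, and that of cad also without control 2.

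Of 40 chitin metabolism genes 7 fell: Cda5 at -1.31, Cht7 at -1.18, Nagk at -1.08, exp at -1.07, Chs2 at -0.93, obst-A at -0.84 and Gfat1 at -0.82. Of the 33 others, 28 lay below the median of all tests. Fry, whose p comes from rotations where an exact test of 3 against 3 cannot go below 0.1, gave p = 0.0481. Adjusted over the 5 families this was 0.0801, which does not pass. After median difference centring fry's unadjusted p was 0.028, also lower. Of 32 membrane lipid enzymes 6 fell: Fa2h, with means of 10.14 and 8.64, bwa at -1.17, sws at -1.01, Pect at -0.92, Cerk at -0.91 and eas at -0.78. Of the 26 others 16 lay below the median of all tests, with fry's p at 0.242 by rotations, not an exact test (0.686 after that centring). All 13 of these calls ended without control 1 or control 2, and all but those of Cda5, Fa2h and Pect without gain 1.

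Smaller lipid families and autophagy genes were tested in the same way. Of 10 fatty acid elongase genes 3 fell, sit at -3.17, CG5326 at -2.06 and CG31522 at -1.28. With sit and CG5326, which prompted the test, taken out, p by fry's rotations, not an exact test, was 0.013 (0.0382 adjusted over the 5 families), but CG31522 was then still among the 8 left. With CG31522 out too, 6 of 7 lay below the median of all tests, with a median of -0.42, and p was 0.0385 by rotations, not an exact test (0.0801 adjusted, 0.0981 after median difference centring), which does not pass. Of 6 phosphatidate phosphatase genes CG11438 and laza fell, at -2.69 and -1.99; of the 4 others 3 lay below the median of all tests, with a median of -0.51. There p was 0.0153 by rotations, not an exact test (0.0138 after that centring), and the adjusted value was 0.0382. Taking CG31522 out of the elongases changed no phosphatase value but moved the adjusted one to 0.0764, so whether this family passes depends on that adjustment and stays open. Of 22 autophagy genes Atg1 and BNIP3 rose by 0.87 and 0.73. Of the 20 others 8 lay below the median of all tests, with a median of -0.09, and fry pointed down as deposited (p = 0.726 by rotations, not an exact test) and up after that centring (p = 0.162). A change beyond the called genes was not shown for elongase and autophagy genes, and without control 1 or control 2 the calls of sit, CG5326, CG31522, laza, Atg1 and BNIP3 ended. That of CG5326 also ended with the mean of its probe sets.

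Among 6988 tested genes placed in order, called genes lay next to each other in 22 pairs. The median over 10000 random placements was 11 (one-sided permutation p = 0.0015). Genes not tested were skipped, so other genes can lie between the members of a pair, as between betaTry and iotaTry. A block of host-strain or insertion-linked sequence could give such pairs, and a run of 4 called genes was there, Fancl, Npc2e, Npc2d and Npc2c. That run holds 3 genes of 1 family, and epsilonTry and betaTry, Cpr67Fa1 and Cpr67Fa2, and laza and CG11438 are pairs of relatives too, so a block of sequence and related genes that move together cannot be told apart from the 22 pairs. Of the 22 pairs 16 were lower in both genes, 1 was higher in both and 5 differed in direction, among them Zip102B and Rnf11, at 4.46 and -0.98.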
